A study of Oryza sativa with 6 samples.

How the data were processed

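The series holds 6 RNA-seq libraries of rice leaves, 3 treated with ShSDH1 protein and 3 with pCold TF protein as the control, each for 6 h. Groups and replicate numbers were taken from the sample titles, and each column was matched to its sample through the library name in the sample descriptions.

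The authors deposited 1 table for the whole series, with FPKM values (fragments scaled to gene length in kilobases and to the mapped fragments of the library) in 1 column per library, and replicates were not pooled. The aligner, the counting tool and the annotation are not given in the sources used here. The only genome builds in the submitters' processing notes are GRCm38 and mm10, which are mouse builds. The samples are rice and the gene identifiers begin with OsR498, so the notes do not state the build behind the values. Per the labels' protocols, libraries were made with the VAHTS Universal V5 kit, and a second sentence of the same protocol names a SMARTER mRNA-Seq kit. Whether counting used strand is not stated, so reads of overlapping and antisense genes, or of near-identical copies, may not have been told apart.

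FPKM scales each library to its total fragments, so that a fall in a few abundant genes tends to raise the values of all others. The FPKM sums still differed, from 445711 in ShSDH1 replicate 3 to 462277 in ShSDH1 replicate 2. No depth was stated with the FPKM values, and it was read from the values themselves. In genes at under 0.1 FPKM the ratio of 2 libraries took a few sharp values, which whole fragment numbers give when divided by a fixed gene length. The size of 1 fragment in each library followed from these ratios, and the total depth was the largest for which gene lengths came out as whole bases. All 25303 genes above 0 in at least 4 libraries (100.0%) then had a whole length and fragment numbers within 0.02 of a whole number. The fragments of these genes summed to 99.1% of the computed total in every library. In simulated FPKM values of 6000 genes in 6 libraries, total depth was recovered to within 5.0e-07% and 99.0% of the recovered lengths were exactly right. These depths served to give the precision of the FPKM values, a length check and an added test. The mean depth was 39104778 fragments in Control and 37022213 in ShSDH1, and the deepest library had 1.24 times the fragments of the shallowest. Fragment numbers cover counting error only, since fragments are not marked as independent molecules.

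Because FPKM are not counts, the test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) on log2(FPKM + 1). It was run over the 17247 genes with at least 1 FPKM in 3 or more of the 6 libraries, and 11764 genes were not tested. P-values are two-sided and Benjamini-Hochberg adjusted over all tested genes, with a threshold of 0.05. A log2 fold change on this scale understates the change of genes at low FPKM. The test was also run on simulated data with the real gene means and spreads and 200 changed genes among the 17247. It recovered 65.7% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 100% of those changed 4-fold, with 9 false calls among 181. Simulated noise was independent between genes, with no shift of whole libraries, and far fewer genes changed than were called in the data. These rates may therefore not hold for the data. Exact tests and intervals used SciPy 1.17.1 and pandas 2.3.3 in Python 3.11.15, and figures used matplotlib 3.10.9.

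The test, the filter, the named-gene rule and the first set of alternatives were fixed before the data were examined. The rule named the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, with non-overlapping groups and a mean of at least 1 FPKM in the higher group. It also named members of 28 gene lists and a panel of rice defence genes. The identifiers of the table matched 0 of the 39387 genes in the gene name table used here, so no list could be resolved to genes, no gene set test was run, and only 4 identifiers are printed. Groups by expression level, by gene length and of the 100 most abundant genes were chosen after the table had been seen.

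Alternatives were pseudocounts of 0.1 and 0.01, no filter, a filter at 5 FPKM, rescaling to TPM, quantile normalization, median-ratio size factors computed on FPKM, other variance models, a replicate block, a threshold of 0.01, a 2-fold minimum, and leaving out each library in turn. Added after the data had been seen were limma's voom on the implied fragments and a scaling that leaves out the 100 most abundant genes. The same replicate numbers occur in both groups. Deviations from the group means correlated at 0.18, 0.27 and -0.02 between libraries with the numbers 1, 2 and 3. Library pairs with unlike numbers ran from -0.29 to 0.15, so numbers 1 and 2 lay above all of them and number 3 did not. Whether the numbers pair the libraries is therefore not settled, and the main test took no pairing.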

Results

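RNA was sequenced from leaves of 2-week-old rice seedlings, 6 h after treatment with a purified protein. A group of 3 libraries came from seedlings given ShSDH1, which the series title describes as an oxidoreductase of the rice endophyte OsiSh-2. The other group of 3 libraries came from seedlings given the pCold TF protein, the product of an expression vector that encodes a trigger factor chaperone as a solubility tag. The pCold TF libraries are the controls and are called Control here. The design implies a single comparison, ShSDH1 against Control, which asks which leaf genes differ in transcript level between the proteins. Nothing in the labels says whether libraries of a group came from separate plants, pools or days, so p-values measure the spread between these libraries, which may be partly technical.

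Expression values were deposited as FPKM for 29011 genes, each above 0 in at least 1 library. Low FPKM values fell on steps of whole fragments, from which totals of 39161994, 36971745 and 41180596 fragments were computed for Control replicates 1, 2 and 3. The same steps gave 35635022, 41776866 and 33654750 fragments for ShSDH1 replicates 1, 2 and 3. A gene of the median length of 2030 bases then had 68.3 fragments behind 1 FPKM in the shallowest library, a counting error of 12.1% of the value. Between 16856 and 17343 genes reached 1 FPKM in each library, and 17247 genes with at least 1 FPKM in 3 or more libraries were tested.

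The libraries separated by treatment. Pearson correlations of log2(FPKM + 1) across the tested genes were 0.990 to 0.993 among the Control libraries, 0.987 to 0.995 among the ShSDH1 libraries and 0.976 to 0.985 between the groups. The first principal component held 49.7% of the variance and placed the Control libraries at -20.4, -19.0 and -11.5 and the ShSDH1 libraries at 16.6, 18.8 and 15.5. The second component held 23.8% and set ShSDH1 replicate 2, at -21.8, apart from the other ShSDH1 libraries, at 11.2 and 10.9. Control replicate 3 was the Control library nearest to the ShSDH1 group on the first component. No pair of libraries held identical values.

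**Figure D1:**
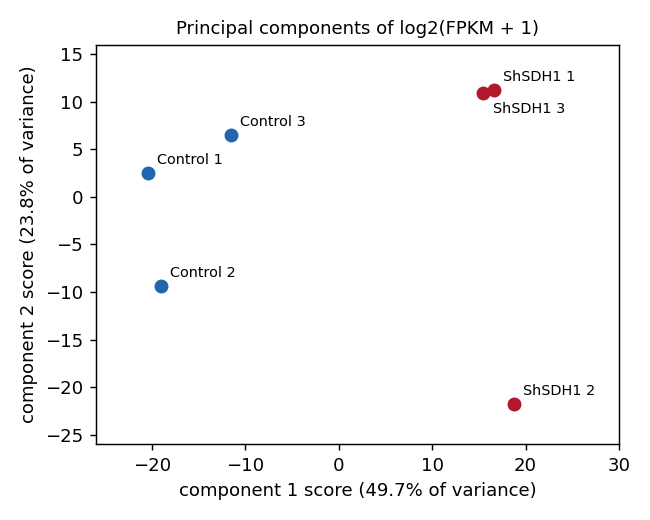
Scores of the 6 libraries on the first 2 principal components of log2(FPKM + 1) over the 17247 tested genes, with Control in blue and ShSDH1 in red. The groups lie on opposite sides of 0 on component 1, and ShSDH1 replicate 2 lies at -21.8 on component 2.

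After 6 h with ShSDH1, 1759 leaf genes (10.2% of those tested) were higher and 647 (3.8%) were lower than with the control protein, at an adjusted p under 0.05 in limma with Benjamini-Hochberg adjustment. Most of these differences were small. The median higher gene rose 1.34-fold and the median lower gene fell 1.30-fold on the log2(FPKM + 1) scale, with interquartile ranges of 1.26 to 1.46-fold and 1.23 to 1.41-fold. A change of at least 2-fold was found in 68 higher and 14 lower genes. That count depended on the offset and scale of the values: it was 137 and 34 with a pseudocount of 0.1, 145 and 38 with 0.01, 101 and 23 after rescaling to TPM and 140 and 37 with voom on implied fragments. All 3 ShSDH1 libraries lay above all 3 Control libraries in 1758 of the 1759 higher genes, and below them in all 647 lower genes. Over all tested genes the groups did not overlap in 4032 genes with ShSDH1 above and 2032 with ShSDH1 below, 35.2% of genes, where chance gives 10% for 3 against 3.

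The share of calls that were higher depended on how the libraries were scaled. With the FPKM as deposited, 73.1% of the differing genes were higher. With median-ratio size factors the split was 1165 higher and 883 lower (56.9% higher), and with quantile normalization it was 1252 higher and 984 lower (56.0% higher). The number of calls also depended on single libraries: 562 genes differed without Control replicate 1, 817 without Control replicate 2, 823 without ShSDH1 replicate 1 1478 without ShSDH1 replicate 3, 1989 without ShSDH1 replicate 2 and 2778 without Control replicate 3. Of the 562 genes, 560 were also among the 2406 found with all libraries, in the same direction.

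**Figure D2:**
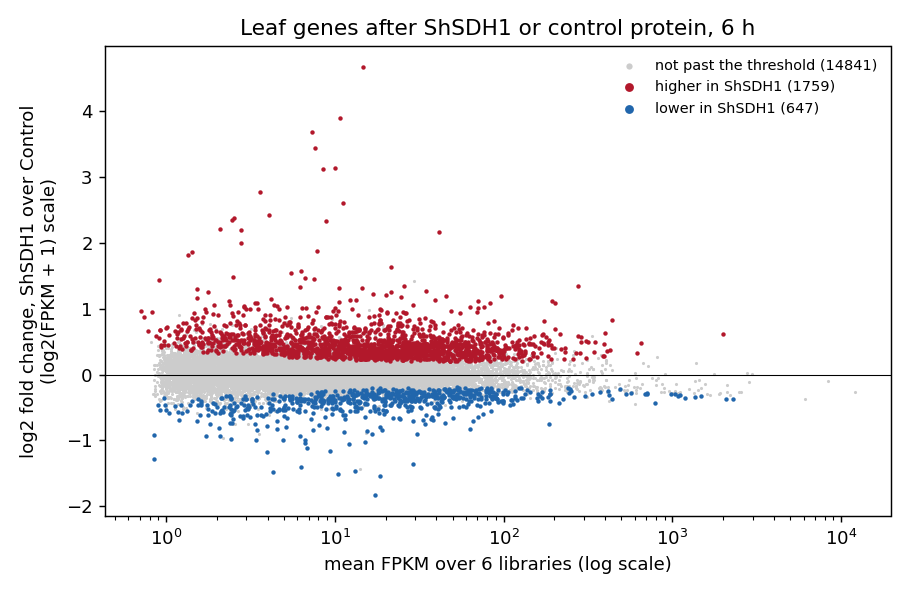
Log2 fold change of ShSDH1 over Control on the log2(FPKM + 1) scale, against the mean FPKM over the 6 libraries on a log axis, with 1 point per tested gene. The 1759 higher genes (red) include a tail of 68 genes with at least a 2-fold rise, and the 647 lower genes (blue) reach down to -1.83.

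The deposited table names genes only by identifiers that begin with OsR498, and it pairs none of them with a gene name or function. None of the 29011 identifiers (0) matched the gene name table used here, so the products and genome positions of the genes below are not given. The 2 most raised and the 2 most lowered genes are reported by identifier and the others as groups. Genes are ranked by log2 fold change on the log2(FPKM + 1) scale, which ranks genes at low FPKM below others with the same ratio of means.

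The most raised gene, OsR498G1018152700.01, was close to silent in Control leaves and well expressed with ShSDH1. Its mean was 0.07 ± 0.10 FPKM (SD, n = 3) in Control and 29.3 ± 17.7 FPKM (SD, n = 3) with ShSDH1, a 447-fold ratio of means that rests on 8, 0 and 1 implied fragments in the Control libraries. The ShSDH1 libraries had 1014, 703 and 1911 fragments. Its log2 fold change on the log2(FPKM + 1) scale was 4.67 ± 0.35 (SE), with a limma adjusted p of 0.000913. The gene next in rank, OsR498G1220846000.01, went from 0.39 ± 0.30 to 21.17 ± 10.34 FPKM (SD, n = 3 each), a 54.5-fold ratio of means. Its log2 fold change was 3.90 ± 0.33 (SE) and its limma adjusted p was 0.00127.

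On the log2(FPKM + 1) scale the largest falls were smaller than the largest rises. OsR498G0917463600.01 fell from 27.56 ± 3.15 FPKM in Control to 7.01 ± 0.29 FPKM with ShSDH1 (SD, n = 3 each), which was 3.93-fold lower. Its log2 fold change was -1.83 ± 0.09 (SE), with a limma adjusted p of 0.000349. OsR498G0917462400.01 fell from 28.10 ± 3.33 to 8.94 ± 0.97 FPKM (SD, n = 3 each), which was 3.14-fold lower. Its log2 fold change was -1.55 ± 0.10 (SE), with a limma adjusted p of 0.000781. These 2 lowered genes stood next to each other in identifier order among the tested genes.

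**Figure D3:**
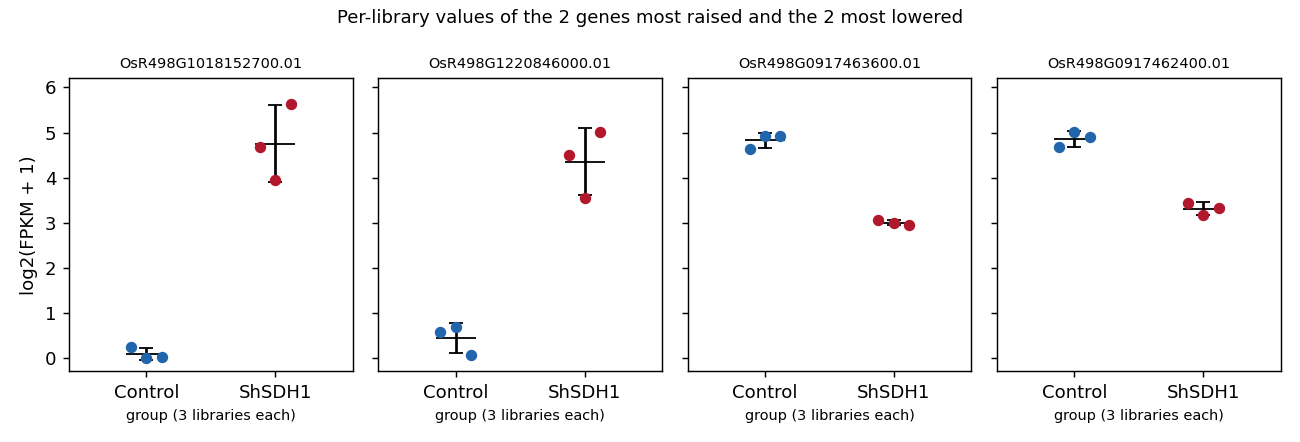
Values of log2(FPKM + 1) in each library for the 2 most raised genes (left pair of panels) and the 2 most lowered genes (right pair), with Control in blue and ShSDH1 in red. Points are libraries, horizontal bars are group means and whiskers are 1 SD (n = 3), and the raised genes spread more widely among the ShSDH1 libraries than the lowered genes do.

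The 8 genes next in rank among the raised had Control means of 0.00 to 2.50 FPKM and ShSDH1 means of 4.95 to 19.79 FPKM, with log2 fold changes from 2.38 to 3.68. Ratios of means of 101 and 56.2 in 2 of these genes exceeded the 54.5 of the gene ranked above them, but rest on 3, 9 and 5 and on 14, 3 and 0 implied fragments in the Control libraries. Another of the 8 genes was listed at 0 in all Control libraries, so no ratio of means can be given for it. Among the 10 most raised genes, ShSDH1 replicate 3 was the highest ShSDH1 library in 9 and ShSDH1 replicate 2 the lowest in 9. The highest ShSDH1 library exceeded the lowest by a median of 3.16 times in these genes. The 8 genes next in rank among the lowered had Control means of 1.63 to 42.89 FPKM and ShSDH1 means of 0.07 to 15.64 FPKM. By ratio of means the largest fall among the 10 was 23.5-fold, in a gene that went from 1.63 to 0.07 FPKM, the latter on 7, 18 and 4 implied fragments. Among the 10 most lowered genes the highest ShSDH1 library exceeded the lowest by a median of 1.32 times. The largest limma adjusted p was 0.044 among the 10 raised genes and 0.007 among the 10 lowered genes.

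Genes that rose at least 2-fold had a low median level in Control, with a wide range. Of the 68, 20 had a Control mean under 1 FPKM, and the median of their group means was 2.69 FPKM in Control and 13.43 FPKM with ShSDH1. The most abundant of them went from a mean of 156.1 FPKM in Control to 396.5 FPKM with ShSDH1. The 14 genes that fell at least 2-fold had a median group mean of 14.72 FPKM in Control and 5.22 FPKM with ShSDH1, and 1 of them had a ShSDH1 mean under 1 FPKM. All 82 genes had groups that did not overlap. Over every listed gene, 2 were listed at 0 in all Control libraries and at 1 FPKM or more in all ShSDH1 libraries, and 0 showed the opposite. The first of these had 13.29, 6.22 and 2.13 FPKM in ShSDH1 replicates 1, 2 and 3, and the other had 1.84, 1.91 and 4.37 FPKM. Their limma adjusted p were 0.00834 and 0.00406.

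Differing genes were found at every expression level. When tested genes were divided into 5 groups of equal size by mean FPKM, 6.4% differed in the lowest group and 27.1% in the highest. The highest group, from 25.64 FPKM upwards, held 659 higher and 277 lower genes, and the lowest group, up to 2.7 FPKM, held 159 higher and 62 lower genes. The share of calls that were higher lay between 70.4% and 76.5% over the 5 groups.

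Among the most abundant transcripts, unlike the rest, falls outnumbered rises with the FPKM as deposited and with median-ratio factors, but not with quantile normalization. Of the 100 genes with the highest mean FPKM, 19 fell, 7 rose and 74 did not pass the test, with a median log2 fold change of -0.23. Among the other genes 1752 rose and 628 fell (Fisher's exact test of the 2 splits, two-sided, p = 1.05e-06). This test counts genes as independent, although all come from the same 6 libraries and FPKM ties the abundant genes to the others. Its p therefore overstates the evidence. The 100 genes took 28.9% ± 1.3 (SD, n = 3) of all FPKM in Control and 25.7% ± 1.2 (SD, n = 3) with ShSDH1. Every Control library was above every ShSDH1 library, and the exact two-sided permutation p of 0.10 is the smallest that 3 against 3 allows. With median-ratio size factors 12 of the 100 genes fell and 3 rose. With quantile normalization 5 fell and 10 rose, and their median log2 fold change was -0.04. Quantile normalization gives every library the same value at each rank, which largely removes a joint fall of the most abundant genes. Its split therefore cannot decide whether these genes fell.

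Gene length, as read from the FPKM steps, differed little between the directions. The median was 1952 bases in higher genes, 1891 bases in lower genes and 2291 bases in genes that did not pass the test. In 5 length groups of nearly equal size the share of calls that were higher ran from 68.3% (exact 95% confidence interval 62.6 to 73.6%) in the longest genes to 77.1% (73.0 to 80.8%) in the middle group. The shortest group held 422 higher and 189 lower genes, and the longest held 200 higher and 93 lower genes.

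**Figure D4:**
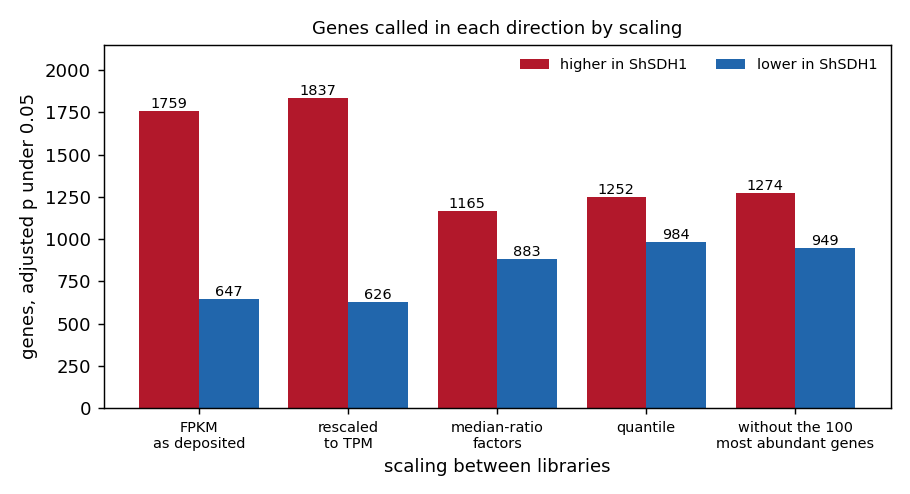
Number of genes higher (red) and lower (blue) with ShSDH1 at an adjusted p under 0.05, under 5 ways of scaling the libraries to each other. Higher genes outnumber lower genes in each, and their share runs from 56.0% with quantile normalization (1252 against 984) to 74.6% after rescaling to TPM (1837 against 626).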

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

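The tests with voom, with the scaling that leaves out the 100 most abundant genes, and of the library correlations were chosen after the data had been seen. The count of 2406 differing genes stayed within 1.5 times under 13 of 20 alternatives. It was 1489 with no filter on low values (29011 genes tested), 592 at an adjusted p under 0.01 and 82 with a 2-fold minimum, and ranged from 562 (without Control replicate 1) to 2778 (without Control replicate 3) when a library was left out. Leaving out a library also removes samples, and what part of each fall comes from that was not tested. The replicate block gave 2239 genes, 2016 of them shared with the 2406, and the 4 named genes passed under it. In deviations from the group means, Control replicates 1 and 2 correlated best with the ShSDH1 library of their own number. Control replicate 3 did not. The count of 82 genes with at least a 2-fold change was 171 and 183 with pseudocounts of 0.1 and 0.01, 124 after rescaling to TPM and 177 with voom on implied fragments, since a smaller offset relative to the values shrinks low genes less. Voom called 2424 genes, 2248 of them shared. The 4 named genes kept their direction and passed the threshold in all 19 alternatives run on them, but the size of the rises depended on the offset: with pseudocounts of 0.1 and 0.01 and with voom the log2 fold change was 7.44, 9.39 and 9.28 for OsR498G1018152700.01, against 4.67, and 5.59, 6.16 and 6.12 for OsR498G1220846000.01, against 3.90. Adjusted p ranged from 0.000301 to 0.0118 for OsR498G1018152700.01, from 0.000703 to 0.0118 for OsR498G1220846000.01, from 0.000115 to 0.00573 for OsR498G0917463600.01 and from 0.000298 to 0.00694 for OsR498G0917462400.01. The mean correlation between groups, 0.982, was 0.976 and 0.972 with pseudocounts of 0.1 and 0.01, 0.991 with no filter and 0.974 with a filter at 5 FPKM; the cause was not tested. The planned gene list tests and their alternatives were not run, because no identifier matched a name. The median log2 fold change of all genes was 0.042, -0.009 with median-ratio factors and -0.015 with quantile normalization. Of the 10 splits of the 6 samples into 3 and 3, the real split, 1 of the 10, gave 2406 genes and 82 genes with at least a 2-fold change. The highest of the others gave 0 of each. Each of the others mixes Control and ShSDH1 libraries, so the difference between treatments adds to their spread and makes calls unlikely. At an unadjusted limma p under 0.05 the others had 173 to 1402 genes and the real split 5069. The 1402 came from Control replicates 1 and 2 with ShSDH1 replicate 2 against the rest. A share under 0.05 cannot be reached with 10 splits.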

Other observations

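All tests of this part were chosen after the table had been seen, and all but the test of gene length after the result they measure. Genes that differed stood next to each other in identifier order more often than shuffling gave. Among the 17001 tested genes of the main number series, 236 neighbouring pairs were both higher against a mean of 176.7 in 10000 shuffles within expression groups, and 55 pairs were both lower against 23.7. The smallest p that these shuffles can give, 0.0001, was reached in each direction (one-sided), which argues against chance placement. The most raised gene, OsR498G1018152700.01, had raised genes on both sides. The neighbour before it went from 0.03 to 4.89 FPKM, with a log2 fold change of 2.35 ± 0.36 (SE) and a limma adjusted p of 0.00707. The neighbour after it went from 0.14 to 14.56 FPKM, with 3.68 ± 0.28 (SE) and a limma adjusted p of 0.000913. The neighbours of OsR498G1220846000.01 had log2 fold changes of 0.18 ± 0.43 and 0.12 ± 0.08 (SE). That identifier order follows position along a chromosome is an assumption, since no coordinates were used here.

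Reads shared between near-identical copies of like length are a technical explanation for neighbouring pairs. If such copies made the whole excess of pairs, 34.4% of pairs that were both higher would have lengths within 10% of each other. The share was 14.8% (exact 95% confidence interval 10.6 to 20.0%), against 12.4% of all neighbouring pairs. For pairs that were both lower the share needed was 62.3% and the share found was 18.2% (9.1 to 30.9%), so both directions argue against such copies as the whole source. Overlapping gene models and copies of unlike length stay open, as does the hypothesis that neighbouring genes may respond together to ShSDH1.

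More differing genes were higher (1759) than lower (647). A candidate explanation is the scaling: the 100 most abundant genes took less of the FPKM with ShSDH1. That raises every other gene if these 100 genes also took a smaller share of the fragments, which was not computed. With these genes left out of the scaling, 57.3% of differing genes were higher in place of 73.1%, but median-ratio factors, which single out no genes, gave 56.9%. FPKM hold no absolute amounts, so a fall of these 100 genes and a broad rise of the others cannot be told apart. Leaving the 100 genes out of the scaling moved the median log2 fold change of all genes only from 0.042 to -0.011. That shift is small beside a 2-fold change. Of the genes with at least a 2-fold change, 75.7% (56 of 74, exact 95% confidence interval 64.3 to 84.9%) were still higher, against 82.9% before. The rescaling took 68 higher and 14 lower genes to 56 and 18. A shift this small can mainly move genes near the 2-fold limit or the threshold, so the share is no separate test of the scaling. Gene length is argued against as the whole source of the excess in the FPKM as deposited. In each of 5 length groups at least 68.3% of differing genes were higher. Length was not without a link, as the median log2 fold change went from 0.06 in the shortest group to 0.0 in the longest. This trend was not examined library by library, so ShSDH1 replicate 2, apart on the second component, may carry part of it. The length values are from the FPKM as deposited, where the scaling may lift all length groups. The smaller excess under the other scalings was not tested against length. Whether the fall of abundant transcripts is a response to ShSDH1 was not tested.

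Control replicate 3 lay nearer to ShSDH1 than the other Control libraries did. It was the highest Control library in 1264 of the 1759 higher genes and the lowest in 363 of the 647 lower genes. Scaling may share in the count of 1264. The median-ratio size factor of Control replicate 3 was 1.008, against 0.973 and 0.965 for Control replicates 1 and 2 and 1.001 to 1.039 for ShSDH1. A uniform rise in FPKM would not make this library the lowest in lower genes. What part scaling plays was not tested. Among the 2778 genes called without Control replicate 3, its median position was 0.34. The scale is linear in FPKM and runs from the other Control libraries (0) to the ShSDH1 mean (1). Control replicates 1 and 2 were at -0.11 and 0.01, but over the 562 and 817 genes called without each of them. These positions rest on different genes and are not directly comparable. Genes were also chosen because the other Control libraries differed from ShSDH1, which by itself can move the library left out towards ShSDH1. If a mixture of RNA or reads from ShSDH1 leaves made the whole 0.34 in Control replicate 3, strongly raised genes would lie as far. The 13 genes changed at least 4-fold on the log2(FPKM + 1) scale had a median position of -0.01 (interquartile range -0.03 to -0.01), which argues against a mixture. The deviations of Control 3 and ShSDH1 3 correlated at -0.02, within the range of -0.29 to 0.15 of library pairs with unlike numbers, so a shared day or batch of the libraries numbered 3 stays open, as does a difference between the plants or in handling.

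The strongly raised genes set the ShSDH1 libraries apart in another way. Positions here are also linear in FPKM, where spread among high values counts for more than on the log2(FPKM + 1) scale. In the 18 genes changed at least 4-fold without ShSDH1 replicate 2, that library had a median position of 0.61 on the way from the other ShSDH1 libraries to Control. Over all 1989 genes called without ShSDH1 replicate 2 the median was 0.03. ShSDH1 replicate 3 lay at -0.82 in the 9 such genes called without it, beyond the other ShSDH1 libraries. Over all 1478 genes called without it the median was 0.23, towards Control. Choosing genes without a library can by itself move that library towards the other group.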
